A study of Mus musculus with 6 samples.

How the data were processed

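Poly(A) RNA of 6 mouse MDSC cultures (3 transfected with mtDNA, 3 blank) was sequenced as single-end reads of 75 bases from directional libraries, per the labels' protocols. The deposited values are whole-number read counts per gene, not normalized, in a single table with 1 column per library. Alignment with STAR 2.7.10a to GRCm39, quality control with FastQC and use of DESeq2 are named in the submitters' processing notes, and the column names carry the name of STAR's per-gene count output, per the file headers. The annotation release and the strand setting of the counts are not given in the sources used here. STAR's per-gene counts leave out reads that map to several places, so a gene with a near-identical copy can lose its reads.

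The table has 55359 rows with Ensembl gene IDs and no symbols, and 34210 of them had no read in any library. Symbols came from a GENCODE M21 annotation of the earlier build GRCm38, which matched 52083 IDs and left 3276 without a symbol. Of the 11190 genes tested, 11179 had one. Because that build differs from the one the counts were made on, no coordinates are given, and the annotation served only for names, GC content, gene type and shared sequence. A few genes are listed there under older names, and Sting1 was found as Tmem173. Every column belonged to a labelled sample. No row lacked a gene ID.

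Library totals were 4111620, 4796800 and 4018360 counts for blank 1, 2 and 3 and 4144481, 4848705 and 4911103 for mtDNA 1, 2 and 3. At these depths 3 counts, the floor used where a group had no read, equal 0.611 to 0.747 CPM in a single library, and fold bounds take 3 counts over the 3 libraries of the group. Intervals and floors cover counting error only. Counts of the 6 pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 1.54 to 2.28, p at most 5.36e-268, over genes with at least 20 reads in the pair), so no library was counted as the same library sequenced again. This does not show that they came from separate cultures.

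Groups came from the treatment label. Genes were compared with edgeR 4.0.16 in R 4.3.3: default expression filter, TMM factors (0.947 to 1.05), quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The biological coefficient of variation was 4.54%. CPM values are TMM-scaled and log2 fold changes are mtDNA minus blank, with a standard error taken from the fold change and the test statistic. Lists with at least 5 tested members were compared with all other genes by limma 3.58.1 (camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01), adjusted over 32 lists. The share of counts in mitochondrially encoded protein genes was compared by an exact permutation test over the 20 assignments.

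The 33 lists, the test and the rule for named genes were fixed before the data were examined. The rule took 16 fixed genes, whatever their result. It added the 6 largest rises and the 6 largest falls with adjusted p under 0.05, a mean of at least 1 CPM and no overlap between groups, skipping predicted genes without a symbol and pseudogenes. From each list it took up to 2 risen and 2 fallen members with the smallest p, or the member with the smallest p as a value only. Some genes that the rule picked are left out of the text. Other genes in the text were chosen after their values were seen: Trim25, H2-Eb1, Csf1r, Adgre1, Ly6g and Pecam1 in the results, and those of the closing section.

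Alternatives were median-ratio, upper-quartile and no scaling factors, no filter and a filter of 1 CPM in all 6 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, a test against a fold of 1.2, neighbouring title numbers as a block, estimated correlations, fry, lists without shared members, other definitions of the mitochondrial share, and omission of each library. A loess correction for GC content, omission of an abundant ID without a symbol, and list tests under library totals were added after seeing the data. Sharing of sequence was measured as the percent of 75-base windows of a gene's longest transcript found in transcripts of other genes, with Python 3.11.15.

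The tests were first run on simulated data: negative binomial counts for the 11190 genes with the real library sizes and dispersions from their trend with abundance. Of these genes 200 were changed, as many up as down. The real data had 1996 calls, mostly rises, so the rates below need not hold for them. For this comparison edgeR recovered 34% of genes changed 1.2-fold, 86% of those changed 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 7.07% false among its calls. DESeq2 recovered 14%, 62%, 82% and 94%, with 0.741% false calls. A simulated list of 30 genes shifted by log2 0.3 was called by camera with the preset correlation (adjusted p = 1.7e-21), with an estimated one (0.0143) and by fry (0.00174), and none of 30 unshifted lists was called by any of them. The simulated genes were drawn independently of each other, so these lists held no correlation between genes. They cannot show how often unshifted lists of correlated genes are called, and in the real lists the estimated correlation reached 0.854.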

Results

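Myeloid-derived suppressor cells (MDSCs) are immature myeloid cells that restrain T cell responses. In this study they were grown from the bone marrow of C57BL/6 mice for 4 days with the cytokines GM-CSF and IL-6, each at 40 ng/ml, and the polymorphonuclear fraction was isolated with a commercial MDSC kit. The labels do not give the purity of the isolated cells, so the values describe the cultures as a whole. The re-seeded cells were transfected with mitochondrial DNA (mtDNA) at 250 ng/ml by means of a lipid reagent, or were left as blank cells, and RNA was collected after 12 h. The labels do not say whether blank cells received the reagent, so the comparison covers the DNA together with any effect of the reagent. No library holds cells given another DNA, so a response to mtDNA in particular cannot be told apart from one to any transfected DNA. Each group had 3 RNA-seq libraries, 6 in all. Total counts ranged from 4018360 to 4911103 per library, which makes a single read worth 0.204 to 0.249 CPM (counts scaled to library size), and 16232 to 16734 genes had at least 1 read. Libraries of the same group correlated at Pearson r of 0.989 to 0.991 across genes, which are not independent replicates. The first principal component carried 68.1% of the variance and separated the groups. The second carried 8.97% and set the library mtDNA 1 apart from the other mtDNA libraries. The labels do not state that the libraries came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

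The study asked how mtDNA affects MDSCs. After transfection the cells carried far more RNA of interferon-stimulated genes and, at a low level, of interferon beta itself. Ifnb1 (ENSMUSG00000048806), which encodes the type I interferon beta, had 0 reads in the 3 blank libraries and 37 in the 3 mtDNA libraries, at least 12.4-fold higher when 3 counts over the blank group are taken as the floor (edgeR adjusted p = 1.64e-05). Rsad2 (ENSMUSG00000020641), which encodes the antiviral enzyme viperin, rose from 10.5 ± 5.98 to 657 ± 93.5 CPM (SD, n = 3 libraries per group), a log2 fold change of 6.01 ± 0.17 (SE; edgeR adjusted p = 2.13e-16). Cxcl10 (ENSMUSG00000034855), a chemokine that attracts activated T cells, rose from 3.92 ± 1.36 to 141 ± 16.1 CPM (log2 fold change 5.17 ± 0.15, edgeR adjusted p = 2.13e-16). Isg15, a ubiquitin-like modifier, rose 19.4-fold (log2 4.28 ± 0.13, edgeR adjusted p = 5.53e-16).

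**Figure D1:**
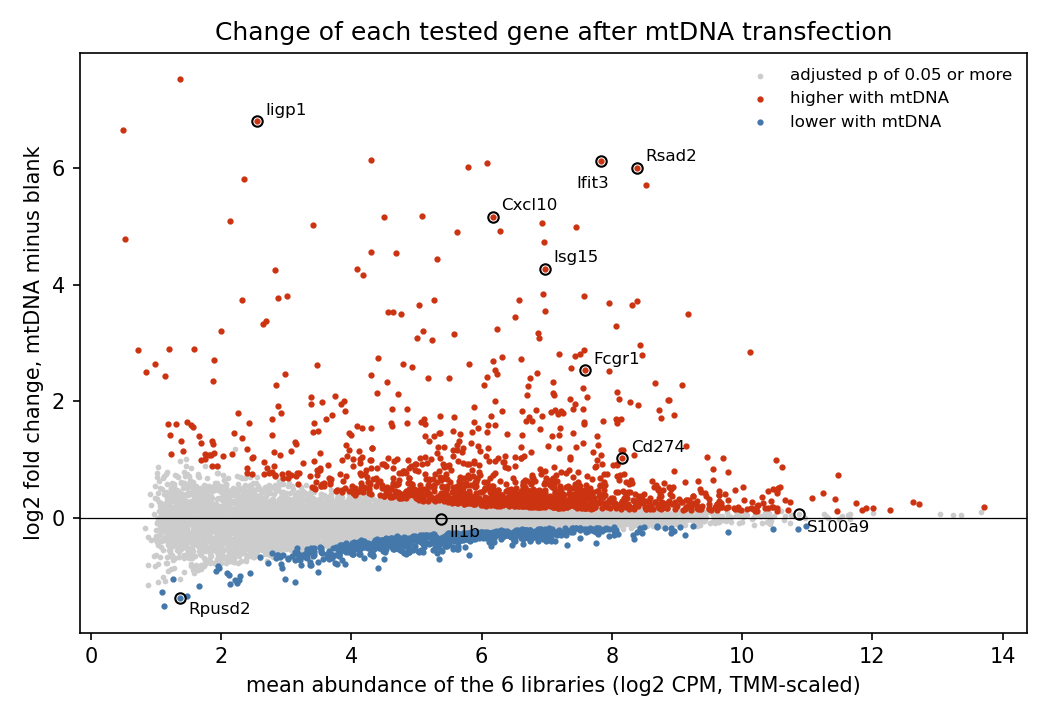
Log2 fold change (mtDNA minus blank) of the 11190 tested genes against their mean abundance in log2 CPM over the 6 libraries, with genes at edgeR adjusted p under 0.05 in red (1327 higher) and blue (669 lower). The labelled rises include Ifit3 at log2 6.12 and Rsad2 at 6.01, whereas the labelled fall, Rpusd2, lies at -1.37. Genes with no read in the blank libraries, such as Ifnb1, are drawn at fitted values that depend on the prior count.

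Of the 11190 genes tested, 1996 changed at an edgeR adjusted p under 0.05, 1327 higher and 669 lower, so that 66.5% of the changes were rises. The rises had a median log2 fold change of 0.44 and the falls of -0.35. The number of falls dropped to 410 without blank 3 and to 437 without mtDNA 1. Changes of at least 2-fold were nearly all rises: 281 genes were higher and 12 lower. The split of the smaller changes depended on the scaling between libraries. With upper-quartile factors 970 genes were higher and 1504 lower, and with library totals alone 861 were higher and 2356 lower. The median log2 fold change of all tested genes was -0.01 under the TMM scaling used here and -0.13 under library totals, so directions are given relative to that shift. Under library totals the median turned from above to below 0 for the lists of MDSC effectors, neutrophil genes, JAK-STAT feedback, MHC class II, apoptosis and p53, heat shock, glycolysis, oxidative phosphorylation, mitochondrially encoded genes and LXR. The same held for the markers of dendritic cells, eosinophils to mast cells, lymphocytes, erythroid cells and stroma. DESeq2 called 928 genes higher and 173 lower, and edgeR's test against a fold of 1.2 called 590 higher and 55 lower.

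By the rule fixed before the data were examined, the largest rises were those of Apol9b, Iigp1, Ifnb1, Ifi205, Ifit3 and Ifit1bl1. Apol9b and Ifnb1 had no read in blank cells, so their ranks rest on fitted values that depend on the prior count. Their lower bounds lie under the 64.3-fold rise of Rsad2, which is not among the 6. Apol9b, of the apolipoprotein L family, had 0 reads in blank cells and 68 in mtDNA cells, at least 22.9-fold higher (edgeR adjusted p = 2.54e-07). It shares 41.6% of its read-length windows with Apol9a, so its count is uncertain. Iigp1, an interferon-inducible GTPase, went from 1 read, in blank 3, to 152 (edgeR adjusted p = 1.52e-09). Ifi205, Ifit3 and Ifit1bl1 rose by log2 6.13 ± 0.38, 6.12 ± 0.18 and 6.08 ± 0.23 (edgeR adjusted p at most 3.19e-11), and Ifi205 by 6.76 without blank 1 and 5.49 without blank 2. Among the largest falls were those of Rpusd2 (log2 -1.37 ± 0.35), Cntnap1 (-1.34 ± 0.35), Cd209c (-1.27 ± 0.43), Lpar5 (-1.13 ± 0.30) and Prpf40b (-1.12 ± 0.26), with edgeR adjusted p of 0.00379 to 0.045. These 5 genes were thinly counted, with 42 to 88 reads over the 3 blank libraries, and none of the 5 passed in DESeq2 (adjusted p of 0.0727 to 0.296). Leaving out mtDNA 1 ended the calls of Lpar5 (adjusted p = 0.0502), Cd209c (0.154) and Cntnap1 (0.0513). Leaving out mtDNA 3 ended those of Lpar5 (0.0676) and Cd209c (0.132). Leaving out blank 3 ended that of Cntnap1 (0.0577), and leaving out blank 2 ended that of Lpar5 (0.0611).

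Interferon-stimulated genes had the largest median change of the 33 lists fixed in advance. All 44 of the 44 tested members rose, also when adjusted over the list alone, and 43 of them by at least 2-fold, with a median log2 fold change of 2.75. The smallest rise was that of Trim25 (0.93 ± 0.066). The list stood above other genes in the camera test (adjusted p = 1.33e-41), and adjusted p = 0.197 with an estimated correlation. Among interferons and their receptors, 4 of 5 tested genes rose and 1 fell, with the same counts adjusted over the list alone. Beside Ifnb1, the receptor subunit gene Ifnar1 rose by log2 0.29 ± 0.054 (edgeR adjusted p = 0.0005). Ifngr1, a subunit of the interferon gamma receptor, fell by 0.22 on the log2 scale (edgeR adjusted p = 0.0152). The call of Ifngr1 ended in DESeq2 (adjusted p = 0.103) and without blank 2 (0.0848), blank 3 (0.0511) or mtDNA 3 (0.0792). The list as a whole had a camera adjusted p of 0.0141, and adjusted p = 0.197 with an estimated correlation.

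**Figure D2:**
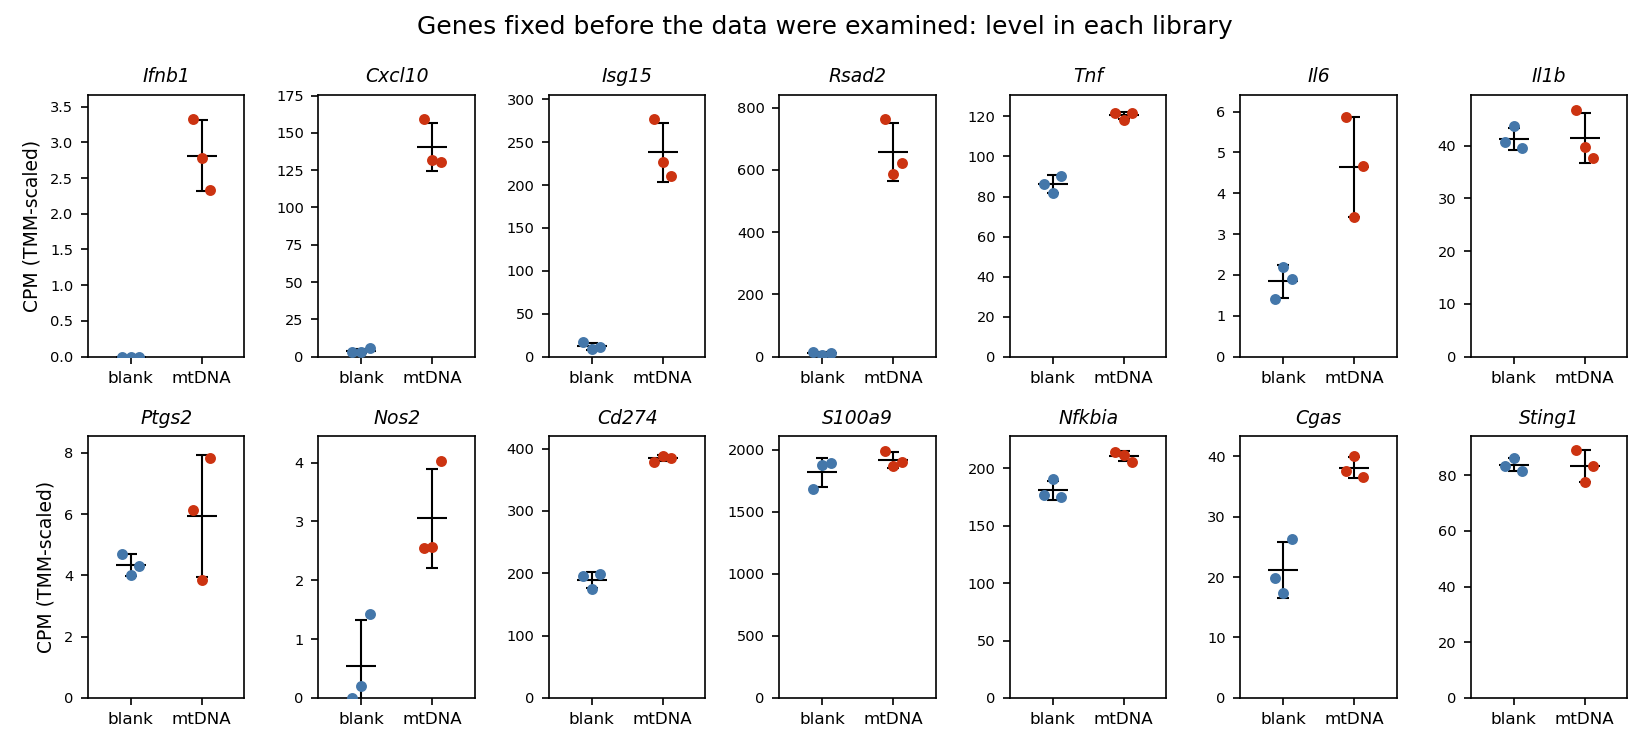
TMM-scaled CPM in each library (points) with the group mean and SD (bars, n = 3) for the 14 tested genes of the 16 fixed before the data were examined, each axis starting at 0. The 3 mtDNA libraries lie above the 3 blank libraries for Ifnb1, Cxcl10, Isg15, Rsad2, Tnf, Il6, Nos2, Cd274, Nfkbia and Cgas, and overlap them for Il1b, Ptgs2, S100a9 and Sting1.

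Genes of nucleic acid sensing rose in 18 of 24 tested members and fell in 0 (18 and 1 when adjusted over the list alone). Ifi203 and Ifi204, which belong to a family of DNA-binding sensors, rose by log2 2.87 ± 0.11 and 2.79 ± 0.12 (edgeR adjusted p = 9.39e-15 and 3.32e-14). Cgas, the cytosolic DNA sensor that makes cyclic GMP-AMP, rose from 21.2 ± 4.57 to 38.1 ± 1.77 CPM (log2 0.86 ± 0.13, edgeR adjusted p = 2.16e-05). Its downstream adaptor Sting1 had 83.7 ± 2.28 and 83.2 ± 5.69 CPM (log2 -0.01 ± 0.070, edgeR adjusted p = 0.922). The list passed the camera test (adjusted p = 1.62e-11), and had adjusted p = 0.197 with an estimated correlation.

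Cytokine and chemokine genes rose in 17 of 24 tested members and fell in 1 (18 and 1 when adjusted over the list alone), with a camera adjusted p of 1.15e-10, and adjusted p = 0.197 with an estimated correlation. Ccl2, a chemokine that recruits monocytes, rose 3.57-fold (log2 1.84 ± 0.11, edgeR adjusted p = 1.47e-11), and Cxcl3, which recruits neutrophils, fell by 0.50 on the log2 scale (edgeR adjusted p = 0.00146). Tnf rose 1.40-fold from 86.2 ± 4.37 to 121 ± 1.86 CPM (edgeR adjusted p = 5.8e-06). Il6 rose from 25 to 61 reads (log2 1.29 ± 0.33, edgeR adjusted p = 0.00808), a call that ended in DESeq2 (adjusted p = 0.0979) and without mtDNA 1 (0.0503). Il1b stood at 41.3 ± 2.09 and 41.4 ± 4.75 CPM (log2 -0.01 ± 0.098, edgeR adjusted p = 0.966). Il10, with 1 read in blank and 5 in mtDNA libraries, was below the count filter, and a difference was not detectable at this depth.

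Genes of the NF-kB pathway rose in 14 of 27 tested members and fell in 0 (19 and 0 when adjusted over the list alone), all by less than 2-fold. Tnfrsf1b, a TNF receptor, rose by log2 0.43 ± 0.049 (edgeR adjusted p = 5.25e-07), and Cflar, an inhibitor of caspase 8, by 0.60 ± 0.078 (edgeR adjusted p = 4.79e-06). Nfkbia, which encodes the NF-kB inhibitor I-kappa-B alpha, rose by 0.22 ± 0.056 (edgeR adjusted p = 0.00816). That call ended with upper-quartile factors (adjusted p = 0.0729), library totals alone (0.188) and without blank 3 (0.0531). The list had a camera adjusted p of 3.56e-06, and adjusted p = 0.14 with an estimated correlation. In the list of JAK-STAT feedback and cytokine receptor genes, 6 of 20 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0983, but 0.0257 with the GC trend removed). Socs1, a feedback inhibitor of cytokine signalling, rose 2.22-fold (log2 1.15 ± 0.086, edgeR adjusted p = 6.45e-10), and the decoy receptor gene Il1r2 rose by log2 0.56 ± 0.059 (edgeR adjusted p = 2.22e-07). Il1r1 and Csf2ra had log2 -0.35 ± 0.11 and -0.14 ± 0.050 (edgeR adjusted p = 0.0335 and 0.0482). Both calls ended in DESeq2 (adjusted p = 0.275 and 0.114) and in 4 and 5 of the 6 omissions of a single library (adjusted p of up to 0.115 without blank 1 for Il1r1 and up to 0.186 without mtDNA 2 for Csf2ra). With the GC trend removed the change of Csf2ra itself shrank to log2 -0.02 ± 0.053 (edgeR adjusted p = 0.834).

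In the list of MDSC suppressive effectors 11 of 27 tested members rose and 0 fell (11 and 2 when adjusted over the list alone). The list also holds regulators and markers, such as Stat3, Hif1a and Trem1, so these counts do not cover suppressive genes alone. Cd274, which encodes the checkpoint ligand PD-L1, rose 2.03-fold from 189 ± 13 to 384 ± 4.84 CPM (log2 1.02 ± 0.056, edgeR adjusted p = 3.21e-12). Lgals9, which encodes the lectin galectin-9, rose 3.09-fold (log2 1.63 ± 0.076, edgeR adjusted p = 2.01e-13). Nos2, the inducible nitric oxide synthase, rose from 7 to 41 reads over the 3 libraries of a group (log2 2.50 ± 0.58, edgeR adjusted p = 0.0037). Of the 7 blank reads 6 were in blank 3, without which the log2 fold change of Nos2 was 4.51. S100a9 had 1819 ± 118 and 1920 ± 65.2 CPM (log2 0.08 ± 0.049, edgeR adjusted p = 0.309), and Ptgs2, which makes prostaglandins, had 4.34 ± 0.35 and 5.94 ± 2.00 CPM (edgeR adjusted p = 0.283). Arg1, which encodes the arginine-degrading enzyme of MDSCs, had 0 reads in all 6 libraries, where 3 counts would be 0.611 to 0.747 CPM. The list passed the camera test (adjusted p = 0.00447), and had adjusted p = 0.197 with an estimated correlation. Its median log2 fold change of 0.10 became -0.01 under library totals.

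Antigen presentation by MHC class I rose in 20 of 23 tested genes and fell in 0 (21 and 0 when adjusted over the list alone), with a median log2 fold change of 0.87. Tap1, a peptide transporter, rose 3.24-fold and Nlrc5, the activator of MHC class I transcription, 4.42-fold (log2 1.70 ± 0.063 and 2.14 ± 0.084, edgeR adjusted p = 9.51e-15 and 1.87e-14). The camera adjusted p was 1.25e-18, and adjusted p = 0.184 with an estimated correlation. For MHC class II, 3 of 11 genes rose, also when adjusted over the list alone (camera adjusted p = 0.0613, but 0.0471 without blank 2 and 0.0243 with the GC trend removed). They were Ctss, a protease of antigen processing (log2 0.51 ± 0.048, edgeR adjusted p = 3.76e-08), H2-Aa and H2-Eb1. The call of H2-Aa (log2 0.17 ± 0.046, edgeR adjusted p = 0.0146) ended under upper-quartile factors (adjusted p = 0.173) and library totals (0.441), and without mtDNA 1 (0.0559) or blank 3 (0.0831). Co-stimulation and dendritic maturation genes rose in 5 of 12 and fell in 0 (8 and 1 when adjusted over the list alone; camera adjusted p = 0.0052), and had adjusted p = 0.319 with an estimated correlation. Cd40 rose 2.68-fold (log2 1.42 ± 0.17, edgeR adjusted p = 9.36e-07), and Marcksl1 by log2 0.48 ± 0.065 (edgeR adjusted p = 8.85e-06).

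**Figure D3:**
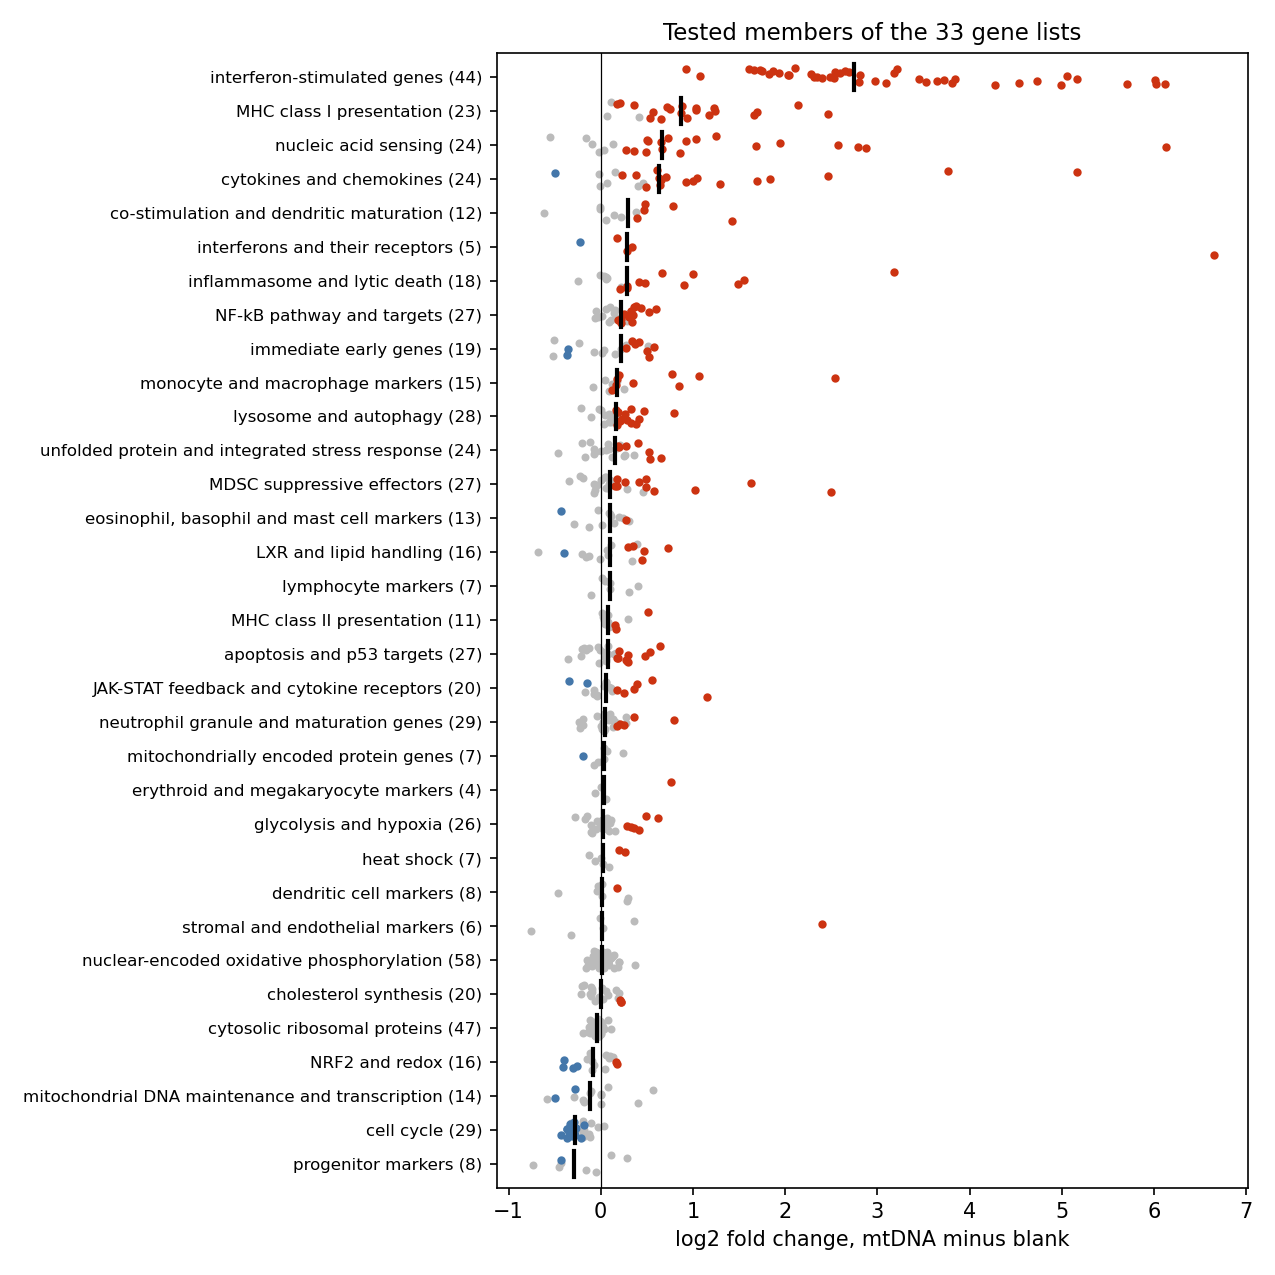
Log2 fold change (mtDNA minus blank) of each tested member of the 33 gene lists, with the number tested in brackets and a black bar at each list's median; red and blue points passed edgeR adjusted p under 0.05, grey points did not. The median is 2.75 for interferon-stimulated genes, 0.87 for MHC class I and -0.28 for cell cycle genes, and these 3 keep their sign under every scaling tried.

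Inflammasome and lytic death genes rose in 11 of 18 tested members and fell in 0, also when adjusted over the list alone (camera adjusted p = 1.76e-06), and had adjusted p = 0.14 with an estimated correlation. Zbp1, a sensor of Z-form nucleic acid, rose 9.05-fold and Mlkl, the effector of necroptosis, 2.93-fold (log2 3.18 ± 0.13 and 1.55 ± 0.10, edgeR adjusted p = 2.8e-14 and 6.95e-11). Apoptosis and p53 target genes rose in 10 of 27 and fell in 0 (11 and 0 when adjusted over the list alone). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by log2 0.53 ± 0.048 (edgeR adjusted p = 1.96e-08) and the kinase gene Plk2 by 0.64 ± 0.093 (edgeR adjusted p = 1.91e-05). The camera adjusted p of this list was 0.0247, and adjusted p = 0.241 with an estimated correlation. Its call also ended under library totals (adjusted p = 0.0623), with neighbouring title numbers as a block (0.0725), and without blank 1 (0.0531), blank 3 (0.0559) or mtDNA 2 (0.0889). Its median of 0.08 became -0.04 under library totals. Genes of the unfolded protein and integrated stress responses rose in 7 of 24 and fell in 0 (8 and 1 when adjusted over the list alone). They included Atf3, a stress-induced transcription factor (log2 0.66 ± 0.055, edgeR adjusted p = 4.28e-09), and Hspa5, the main chaperone of the endoplasmic reticulum (0.52 ± 0.052, edgeR adjusted p = 6.65e-08). The camera adjusted p was 0.0364, and adjusted p = 0.319 with an estimated correlation. The call ended under library totals (adjusted p = 0.0653) and without mtDNA 1 (0.0917) or blank 3 (0.0559).

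Cell cycle genes moved the other way. Of 29 tested genes, 17 fell and 0 rose (19 and 0 when adjusted over the list alone), each by less than 2-fold. Mcm3 and Mcm5, subunits of the replicative helicase, fell by 0.36 and 0.33 on the log2 scale (edgeR adjusted p = 0.000372 and 0.00065). The list median was -0.28 (camera adjusted p = 1e-07), and adjusted p = 0.209 with an estimated correlation. Lysosome and autophagy genes rose in 14 of 28 and fell in 0 (17 and 0 when adjusted over the list alone; camera adjusted p = 1.21e-05), and had adjusted p = 0.332 with an estimated correlation. Npc2, a lysosomal cholesterol carrier, rose 1.73-fold and Grn, which encodes progranulin, 1.38-fold (log2 0.79 ± 0.057 and 0.46 ± 0.046, edgeR adjusted p = 3.52e-10 and 8.21e-08).

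Genes of mitochondrial respiration differed little. None of the 58 tested nuclear genes of oxidative phosphorylation passed in edgeR, over all genes or adjusted over the list alone, and Cox6c had the smallest p (log2 0.14 ± 0.063, edgeR adjusted p = 0.126; camera adjusted p = 0.655). Counts in mitochondrially encoded protein genes made up 1.69% ± 0.0977 of the total in blank and 1.57% ± 0.0324 in mtDNA libraries (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The groups were barely separated, with 1.608% in blank 1 and 1.605% in mtDNA 1. The difference of -0.117 percentage points was -0.0618 without blank 2. Among the 7 tested genes 1 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.954). The fallen gene was mt-Nd5 (log2 -0.19 ± 0.064, edgeR adjusted p = 0.0391), and its libraries overlapped between groups. Its call ended in DESeq2 (adjusted p = 0.388), with robust dispersion (0.168), and without blank 1 (0.122), blank 3 (0.17) or mtDNA 2 (0.269). Another 6 protein genes of mtDNA had 0 or 1 read in total and were not tested. Among genes of mtDNA maintenance and transcription, 2 of 14 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.319). Lonp1, a mitochondrial protease, had log2 -0.27 ± 0.071 and Polrmt, the mitochondrial RNA polymerase, -0.49 ± 0.16 (edgeR adjusted p = 0.00887 and 0.031). In DESeq2 neither passed (adjusted p = 0.113 and 0.23), and the call of Polrmt ended in 4 of the 6 omissions of a library (blank 2, blank 3, mtDNA 1 and mtDNA 3, adjusted p of 0.063 to 0.172). With the GC trend removed Polrmt had log2 -0.41 ± 0.15 (edgeR adjusted p = 0.0665).

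Other metabolic and stress lists did not pass the camera test at its preset correlation and TMM scaling. Glycolysis and hypoxia genes rose in 6 of 26 and fell in 0 (6 and 1 when adjusted over the list alone; camera adjusted p = 0.189), among them the collagen hydroxylase gene P4ha1 (log2 0.62 ± 0.067, edgeR adjusted p = 2.93e-07) and the hexokinase gene Hk3 (0.42 ± 0.063, edgeR adjusted p = 3.4e-05). LXR and lipid handling genes rose in 5 of 16 and fell in 1 (6 and 3 when adjusted over the list alone; camera adjusted p = 0.161). Plin2, a lipid droplet coat protein, and the sterol exporter gene Abcg1 rose by 0.47 ± 0.051 and 0.45 ± 0.056, and the desaturase gene Scd2 fell by 0.39 on the log2 scale (edgeR adjusted p at most 8.91e-05). Among NRF2 and redox genes 2 of 16 rose and 4 fell (3 and 4 when adjusted over the list alone; camera adjusted p = 0.319). Gclm, of glutathione synthesis, and Txnrd1, thioredoxin reductase, fell by 0.30 and 0.26 on the log2 scale (edgeR adjusted p = 6.05e-05 and 0.000592). Immediate early genes rose in 7 of 19 and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.0824). The list passed upward under library totals (camera adjusted p = 0.0355), with the GC trend removed (0.0194) and without blank 2 (0.0253) or mtDNA 3 (0.0493). Klf6 and Dusp1 rose by 0.42 ± 0.048 and 0.57 ± 0.084, and Fosl2 fell by 0.37 (edgeR adjusted p = 8.31e-07, 2.31e-05 and 8.91e-05). The second fall, that of Ier2 (log2 -0.36 ± 0.097, edgeR adjusted p = 0.0128), ended in DESeq2 (adjusted p = 0.08) and without mtDNA 1 (0.0665) or blank 3 (0.0937). With the GC trend removed it was log2 -0.27 ± 0.095 (edgeR adjusted p = 0.0524).

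Cholesterol synthesis genes rose in 3 of 20 and fell in 0, also when adjusted over the list alone (camera adjusted p = 0.894). Heat shock genes rose in 2 of 7, Hspa8 and Bag3, also when adjusted over the list alone (log2 0.20 ± 0.046 and 0.27 ± 0.081, edgeR adjusted p = 0.00402 and 0.0251; camera adjusted p = 0.619). The calls of these 2 genes, and those of the redox genes Sqstm1 (log2 0.16 ± 0.052, edgeR adjusted p = 0.0335) and Prdx1 (0.18 ± 0.061, 0.0434), ended under library totals (adjusted p of 0.178 to 0.524) and upper-quartile factors (0.0662 to 0.241). The call of Bag3 also ended in 5 of the 6 omissions (adjusted p of up to 0.158, without blank 3). For Sqstm1 and Prdx1 the omissions were those of blank 2, blank 3 and mtDNA 1, with adjusted p of up to 0.166 and 0.262. In DESeq2 the calls of Bag3, Sqstm1 and Prdx1 ended too (adjusted p = 0.153, 0.0598 and 0.47), and that of Prdx1 with the GC trend removed (log2 0.16 ± 0.064, edgeR adjusted p = 0.0861). None of 47 cytosolic ribosomal protein genes passed in edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.0968). The list passed downward under library totals (camera adjusted p = 0.00249) and without blank 1 (0.0113). Rpl10a had the smallest p there (log2 -0.19 ± 0.068, edgeR adjusted p = 0.0555), which became 0.00171 under library totals, 0.00736 under upper-quartile factors, 0.0191 without the count filter, 0.0343 with robust dispersion and 0.0059 without blank 3.

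Markers of cell types were measured in the same libraries. Monocyte and macrophage markers rose in 9 of 15 and fell in 0 (10 and 0 when adjusted over the list alone; camera adjusted p = 2.44e-05), and had adjusted p = 0.184 with an estimated correlation. Fcgr1, a high-affinity Fc receptor, rose 5.82-fold (log2 2.54 ± 0.10, edgeR adjusted p = 2.78e-14) and Ly6c2, a surface antigen of inflammatory monocytes, 1.80-fold (log2 0.85 ± 0.054, edgeR adjusted p = 4.89e-11). Csf1r, the M-CSF receptor, had 1424 ± 16 and 1552 ± 3.52 CPM (log2 0.12 ± 0.042), and Adgre1, which encodes F4/80, 501 ± 18 and 535 ± 9.97 CPM (0.09 ± 0.048, edgeR adjusted p = 0.203). Neutrophil granule and maturation genes rose in 5 of 29 and fell in 0 (6 and 1 when adjusted over the list alone; camera adjusted p = 0.0983). The formyl peptide receptor gene Fpr2 rose 1.28-fold (edgeR adjusted p = 0.000216). Ly6g, the surface antigen of mouse neutrophils and polymorphonuclear MDSCs, stood at 4.87 ± 0.95 and 5.81 ± 1.14 CPM (edgeR adjusted p = 0.506).

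Among stromal and endothelial markers 1 of 6 rose and 0 fell (1 and 1 when adjusted over the list alone; camera adjusted p = 0.808). It was Kdr, a VEGF receptor gene, which rose 5.26-fold from 11.6 ± 1.89 to 60.7 ± 5.48 CPM (log2 2.40 ± 0.12, edgeR adjusted p = 1.14e-12), while Pecam1 had log2 0.03 ± 0.096. Eosinophil, basophil and mast cell markers rose in 1 of 13, Mcpt8, and fell in 1, Kit, also when adjusted over the list alone (log2 0.27 ± 0.072 and -0.43 ± 0.11, edgeR adjusted p = 0.0108 and 0.00754; camera adjusted p = 0.495). Kit was also the only fall among 8 progenitor markers, where 0 rose (camera adjusted p = 0.102), with the same counts adjusted over the list alone. Its call ended in DESeq2 (adjusted p = 0.109). Irf8 was the only rise among 8 dendritic cell markers and did not pass when adjusted over the list alone (log2 0.18 ± 0.061, edgeR adjusted p = 0.0472; camera adjusted p = 0.619). The call of Irf8 ended in 5 of the 6 omissions, with adjusted p of up to 0.242 without mtDNA 1, and that of Mcpt8 without mtDNA 2 (0.0599). Both ended under library totals (0.478 and 0.123) and in DESeq2 (0.177 and 0.0962). None of 7 lymphocyte markers passed, over all genes or adjusted over the list alone, and Ms4a1 had the smallest p (log2 0.41 ± 0.29, edgeR adjusted p = 0.38; camera adjusted p = 0.655). Of 4 erythroid and megakaryocyte markers, too few for the list test, Gp9 rose, also when adjusted over the list alone (log2 0.76 ± 0.22, edgeR adjusted p = 0.0197). That call ended in DESeq2 (adjusted p = 0.218) and without blank 3 (0.0882) or mtDNA 3 (0.0896).

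In total 14 of the 32 lists passed the camera test at its preset correlation, 13 upward and 1 downward. With correlations estimated from the data 0 passed after adjustment and 7 had an unadjusted p under 0.05, while fry, which asks whether a list's own genes move on balance, called 21. The 7 lists it added were those of neutrophil genes, JAK-STAT feedback, MHC class II, immediate early genes, glycolysis, LXR and progenitor markers.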

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

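The tests of explanations in this part were chosen after the results were seen, apart from the other splits of the libraries, which were planned. Reads of genes that the count filter left out showed a signal in the mtDNA libraries above the blank ones. The 13 interferon alpha genes below the filter had 0 reads in the 3 blank libraries and 44 in the 3 mtDNA libraries (17, 10 and 17), spread over 6 genes, at least 14.8-fold higher with a floor of 3 counts over the blank group. Members of this family resemble each other, so the sum is firmer than any single gene. Of all 44169 genes below the filter, 90 had a read in every mtDNA library and none in any blank library, against 48 with the opposite pattern. The mtDNA libraries also held more reads in total (13904289 against 12926780), and no chance expectation was worked out for these counts. The 90 genes include Apol9a with 27 reads and Cxcl9 with 5, but also genes with 1 read in each mtDNA library, such as Map2 and Kcnt1.

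Among changes of at least 2-fold rises outnumbered falls. Scaling between libraries would have brought their ratio below 1.5, but its lowest value over 4 scalings was 8.96. These scalings moved the median of all genes only between -0.01 and -0.13 on the log2 scale. That is too little to undo changes of 2-fold, so this test could hardly have come out otherwise. Reads taken up by the induced genes, whose share grew from 1.18% to 4.29% of counts, would lower all other genes alike by 0.046 on the log2 scale under library totals. Genes that fell when a pair of libraries was left out had medians of -0.415 to -0.377 in that pair (upper quartiles at most -0.248), below other genes there too (-0.139 to -0.113). A GC content trend does not account for most of the 669 falls, since 79.1% were still called lower once it was removed, with a median of -0.35 before and -0.34 after (SD 0.19 both times). A true lowering of these genes after transfection stays open as a hypothesis, and an effect of the reagent alone was not tested.

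The mitochondrial genes mt-Co2, mt-Co3, mt-Nd3 and mt-Nd4l had 0 reads and mt-Atp6 had 1 over all 6 libraries, while mt-Co1 had 225435. A candidate explanation is that reads shared with near-identical nuclear copies were dropped as ambiguous. At least 97.8% of the 75-base windows of each of these 5 genes occur in another transcript, against at most 61.5% for the 7 mitochondrial protein genes that were counted. For mt-Atp8, also at 0 reads, 0% of the windows were found in another annotated transcript. Unannotated genomic copies were not searched, so this explanation stays undecided for that gene. The mitochondrial share in the report therefore covers 7 of 13 protein genes. No biological explanation was tested.

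Of 15 tested markers of monocytes and macrophages 9 rose, although a kit for the polymorphonuclear fraction had been used, and the list had camera adjusted p = 0.184 with an estimated correlation. Many of the 15 markers are expressed by monocytic MDSCs too. Their median log2 fold change was 0.18, or 0.06 under library totals, and the furthest rises were those of Fcgr1, Ly6c2, Mertk, Ms4a7 and C1qb. A larger share of these cells alone would raise their markers about alike if all were equally restricted to them, which was not tested. The 15 markers ranged from -0.08 to 2.54, and 6 lay away from the median by more than their 95% interval, 5 of them upward. Markers with some expression in other cells could rise by unequal amounts, so this spread cannot decide whether a share changed. More monocytes or macrophages may add to the rises, and their part cannot be told apart from a response within the cells. The medians of other cell types' lists lay on both sides of 0 under TMM scaling (0.05 for neutrophil genes, -0.29 for progenitor markers). Under library totals, where the median of all genes was -0.13, those of neutrophil, dendritic, eosinophil to mast cell, lymphocyte and progenitor lists all lay below 0 (-0.41 to -0.02).

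The groups of 3 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 1996 changed genes, 293 of them by at least 2-fold, and 14 lists; the highest values of the other splits were 0, 0 and 12. In each case 1 of the 10 splits, the real one, reached its own value. Each of the other splits puts both treatments in both groups. The treatment difference then widens the spread within groups, so counts of 0 genes were nearly fixed in advance. Part of that difference also stays between the groups, so the 12 lists are not a value free of treatment. No conclusion is drawn from this comparison.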

How the results depend on the processing

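The GC correction, the omission of an ID without a symbol, and the list tests under library totals were chosen after seeing the data. The 1996 changed genes became 3217 with library totals alone, 1101 in DESeq2 and 645 in the test against a fold of 1.2, of which 1530, 1093 and 645 were among the 1996. The first follows from scaling that moves the median of all genes to -0.13, and the last from its stricter null hypothesis. The cause of the DESeq2 count was not tested on the real data, though in simulation it recovered fewer small changes. Other settings gave 1942 to 2474. Omitting a library in turn gave 1507 to 1713 changed genes (1097 to 1191 rises and 410 to 522 falls), 281 to 310 changed at least 2-fold, 12 to 16 lists, and a mitochondrial share lower by 0.155 to 0.0618 percentage points (-0.155 without blank 1, -0.0618 without blank 2). The 293 genes changed at least 2-fold ranged from 252 to 335 over all settings. The 14 lists became 0 with estimated correlations, which reached 0.854 for interferon-stimulated genes against the preset 0.01. Lists with estimates below the preset lost their calls too, NF-kB with -0.012 and interferons and their receptors with 0.00141. The unadjusted camera p of these lists still rose, from 7.79e-07 to 0.00517 and from 0.00527 to 0.047. The size of the correlation therefore does not account for all of these losses. Estimating it made the test stricter in some other way, which was not examined. A list that fails under this setting is not thereby shown to be unmoved. Neighbouring title numbers as a replicate block gave 2134, 296 and 13. The labels do not pair them, the deviations of neighbours correlated at 0.07, 0.11 and 0.12, and among named genes and lists the block ended only the call of the apoptosis and p53 list (camera adjusted p = 0.0725) and added that of Rpl10a. It kept 1988 of the 1996 gene calls. No named gene or list passed in both directions, though list medians near 0 changed sign under library totals. Removing the GC trend gave 17 lists, with JAK-STAT feedback, MHC class II and immediate early genes added. Of 86 named and tested genes, 59 kept their side of the threshold under all settings, and 10 of 32 lists did. DESeq2 ended 22 gene calls. Genes below the count filter could not be called, and a change of 1.2-fold was recovered in 34% of simulated genes.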

Other observations

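The lists of this part were written after the values of some members had been seen, and so was the test of ribosome biogenesis genes, so their counts are not independent evidence. In 3 interferon-inducible families every tested member rose. The 15 tested of 19 interferon-inducible GTPases rose, with a median log2 fold change of 2.9, among them Gbp3 (2.69 ± 0.093) and Tgtp2 (5.03 ± 0.33). The 12 tested of 13 PYHIN genes, a family of nucleic acid binding proteins, rose with a median of 3.52, among them Ifi209 (3.30 ± 0.11). All 7 Schlafen genes rose with a median of 2.07, among them Slfn4 (3.68 ± 0.13) and Slfn5 (3.50 ± 0.19). These medians are 2.79, 3.4 and 1.95 under library totals. Of 15 PARP genes 9 rose and 0 fell, led by Parp14 (2.28 ± 0.13) and Parp12 (2.22 ± 0.090), while Parp1 had -0.14 ± 0.075. All 5 VEGF receptor genes rose: Flt4 by log2 3.21 ± 0.39, Kdr by 2.40 ± 0.12, Flt1 by 1.12 ± 0.30, and Nrp1 and Nrp2 by 0.26 each.

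Genes of ribosome biogenesis fell in 26 of 56 tested members and rose in 1, Nol10 (log2 0.43 ± 0.13), with a median of -0.31. Nolc1, a nucleolar protein, fell by 0.64 on the log2 scale and Gar1, of the H/ACA particle, by 0.72. Genes of nucleotide synthesis fell in 11 of 25 and rose in 0, with a median of -0.27, among them Uck2 (-0.42 ± 0.055) and Shmt1 (-0.77 ± 0.18). The falls had been noticed among the 150 falling genes with the smallest p. A wider fall of growth genes was put forward as a hypothesis and tested on the 44 ribosome biogenesis genes outside those 150. They also lay below other genes (median log2 fold change -0.25, camera p = 4.27e-09), but did not pass with an estimated correlation (p = 0.0237, camera adjusted p = 0.0645), so a fall across the group stays open. Leaving out the genes with the smallest p works against finding one. The 47 ribosomal protein genes, with a median of -0.04, did not pass.

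The most abundant transcripts were those of Psap (12615 ± 398 CPM in blank cells), Fth1 and Lyz2 (10335 ± 411 CPM). Mmp12 stood at 4693 CPM, Cd74 at 4025 ± 218 and Gpnmb at 3129 ± 53.9. S100a8 stood at 1698 ± 65.3, Mmp8 at 2545 ± 17.5, Mpo at 433 ± 28.8 and Ly6g at 4.87 ± 0.95 CPM in the same libraries. A low Ly6g beside abundant macrophage transcripts sits poorly with a pure polymorphonuclear fraction, and the identity of the cells was not tested. None of the 75-base windows of Arg1 or Ly6g occurs in another transcript, and Arg1 had 0 reads in all 6 libraries. Trex1, of the nucleic acid sensing list, had 0 reads as well. The reason for the missing Arg1 reads was not found. The window check covers shared sequence only, so 0 counted reads need not mean that the gene was silent.

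An ID without a symbol in the annotation used, ENSMUSG00000119584, had 11071, 10146 and 7543 reads in blank 1, 2 and 3 and 11067, 16394 and 20613 in mtDNA 1, 2 and 3.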
